A study of Mus musculus with 6 samples.

How the data were processed

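Total RNA of mouse uterus was labelled with biotin and hybridised to Affymetrix-type arrays, 3 for floxed control mice and 3 for Notch1 knockout mice. Per the labels' protocols, ovariectomy at 6 weeks of age was followed 2 weeks later by 3 daily injections of 100 ng estradiol, 2 days of rest and 3 daily injections of 1.0 mg MPA with 6.7 ng estradiol. The lining of 1 uterine horn was scratched 6 h after the last injection, and daily MPA with estradiol went on for 1 to 5 days. Per the labels, 5 to 20 µg of RNA entered labelling, from a pool of 3 mice per genotype and treatment.

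The deposited table holds log2 expression values of 45101 probe sets for the 6 arrays, made by the authors with RMA, per the submitters' processing notes. RMA is a method that by design corrects background, normalizes arrays by quantiles and summarises the probes of a probe set. The version, the software and the chip definition are not given in the sources used here. The scale was read from the values, which ran from 2.61 to 14.74. Array medians differed slightly, between 5.74 and 5.91. Arrays have no read depth, so the number of arrays and the brightness of a probe set set the precision. RMA compresses differences of dim probe sets, and its normalization assumes that the arrays share 1 distribution of signal, so a shift of most genes in one direction would be removed. No per-sample column was left out (0 columns).

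The 64 Affymetrix control probe sets were left out of all tests. The platform table paired 34945 of the other probe sets with 1 gene symbol, 932 with several and 9160 with none, and symbols were brought up to date through gene numbers, of which 34741 matched the reference gene table (GRCm38.p6 assembly, used for names, lengths and neighbours). Each of 18193 genes was represented by its probe set with the highest mean over all 6 arrays, with no filter on dim probe sets. Of the 78 genes named in the text that passed the threshold, 49 had more than 1 probe set. A probe set of opposite sign was found for 11 of them, Cdk6, Cenpf, Col1a1, Egfr, Grhl2, Ncoa1, Notch2, Pck1, Prf1, Prrc2c and Ttc28, and none of those probe sets passed an adjusted p of 0.05 in limma.

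Knockout and control arrays were compared with lmFit and eBayes without trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The median SE of a log2 difference was 0.15, and the moderated variance had 3.61 prior degrees of freedom. Notch1 was also tested with an exact permutation test. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 35 lists, then with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way and does not compare the list with other genes. camera called 10 lists, 1 higher and 9 lower. With an estimated correlation 0 were called, and fry called 2, natural killer cell markers and red blood cell genes. In camera with an estimated correlation, the natural killer list had an unadjusted p of 0.0259 in the family of 35.

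The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Notch1 and a panel of 15 other uterine genes, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and all members where a count was 5 or less. Genes outside the rule are said to have been chosen after their values were seen. Alternatives were a block for the replicate number, quantile normalization, centring on array medians, the mean of all probe sets of a gene, a filter for genes above the median level, trended and robust moderation, array weights, leaving out each array, an ordinary two-sample test, and a stricter threshold. A correction for genomic gene length, which subtracts a lowess curve (span 0.5) of each array's deviations on log10 length for 18032 genes with a length, and the 3' to 5' ratio of beta-actin as a covariate were added after the data were seen.

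No pair of arrays held the same value at more than 94 of the 45101 probe sets, so none was deposited more than once. The steps were tested on simulated data with the means and spreads of these arrays, 18193 genes and 200 changed genes in each of 5 runs. For the comparison of knockout with control, 3.6% of genes changed by 0.5 on the log2 scale were recovered, 53.6% at 1, 90% at 2 and 98% at 3, and 4.37% of the calls were false. The noise was drawn independently for each gene, so the simulation held no correlation between genes. Its share of false calls need not hold for the calls made on these arrays. The shares recovered need not hold either, because only 200 genes were changed, while 998 passed on these arrays. Fewer changed genes make the adjusted threshold stricter.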

Results

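Gene expression was measured with 6 Affymetrix-type arrays of mouse uterus RNA, 3 from floxed control mice and 3 from Notch1 knockout mice labelled PRCre/+, a genotype in which Cre recombinase is made from the progesterone receptor locus. The controls are titled Notch1 wildtype and described as floxed, without mention of Cre. Effects of Cre or of its place at the receptor locus therefore cannot be told apart from those of Notch1 loss. Notch1 is a cell surface receptor whose cleaved intracellular part acts on transcription. The mice had their ovaries removed at 6 weeks of age and received estradiol and the progestin MPA, and a scratch of the uterine lining then set off decidualization, the change of uterine stromal cells into the decidua that surrounds an implanting embryo. The series title names the question as the role of Notch1 in cell fate and in completing decidualization. Tissue was collected between day 1 and day 5 after the scratch, and the labels do not give the day of each array or say whether only the scratched horn was used. RNA was pooled from 3 mice per genotype and treatment. Nothing states that each array held a pool of its own, so the p-values measure the spread between these arrays, which may be technical. Array medians lay between 5.74 and 5.91 on the log2 scale, and the number of arrays limits the precision. Differences are log2 values, knockout minus control, with the standard error (SE) from limma and n = 3 arrays per group. A gene is said to have risen or fallen only where its limma adjusted p was below 0.05.

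Notch1 itself was at 8.59, 8.46 and 8.76 in control arrays 1, 2 and 3 and at 8.29, 8.02 and 7.94 in knockout arrays 1, 2 and 3. All 3 knockout arrays lay below all 3 control arrays, with a difference of -0.52 ± 0.14 (SE, n = 3 per group), or 1.43-fold. The limma adjusted p was 0.074, which does not pass 0.05, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give. A dimmer Notch1 probe set differed by -0.25 on the log2 scale, again with no overlap between the groups. Where the probes lie relative to the floxed part of the gene is not given in the sources used here, so a residual signal is no measure of how much of the gene was removed.

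Of 18 natural killer cell markers, 11 rose in the knockout uterus, and camera's call of the list had an adjusted p = 0.514 with an estimated correlation. The granzymes Gzmg, Gzmd, Gzme, Gzmf and Gzmc, serine proteases of cytotoxic granules, rose by 2.53, 2.52, 2.44, 2.26 and 2.18 on the log2 scale, or 4.53-fold to 5.78-fold, and Prf1, the pore-forming protein of the same granules, rose by 2.12 ± 0.31. Of 21 fibroblast markers, 6 fell, among them the collagens Col5a1 at -1.69 ± 0.23 and Col1a1 at -1.47 ± 0.24, and camera's call of that list had an adjusted p = 0.514 with an estimated correlation. Of 24 epithelial markers 5 fell, and of 20 genes in a list of estrogen-induced epithelial genes 4 fell, among them Ehf, an epithelial transcription factor, at -2.53 ± 0.45 and Greb1, an estrogen-responsive gene, at -2.34 ± 0.33. With an estimated correlation camera gave these lists an adjusted p = 0.593 and an adjusted p = 0.514. The arrays measured uterus RNA, so no value here places these falls in one cell type or separates them from a change in the share of a cell type.

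**Figure D1:**
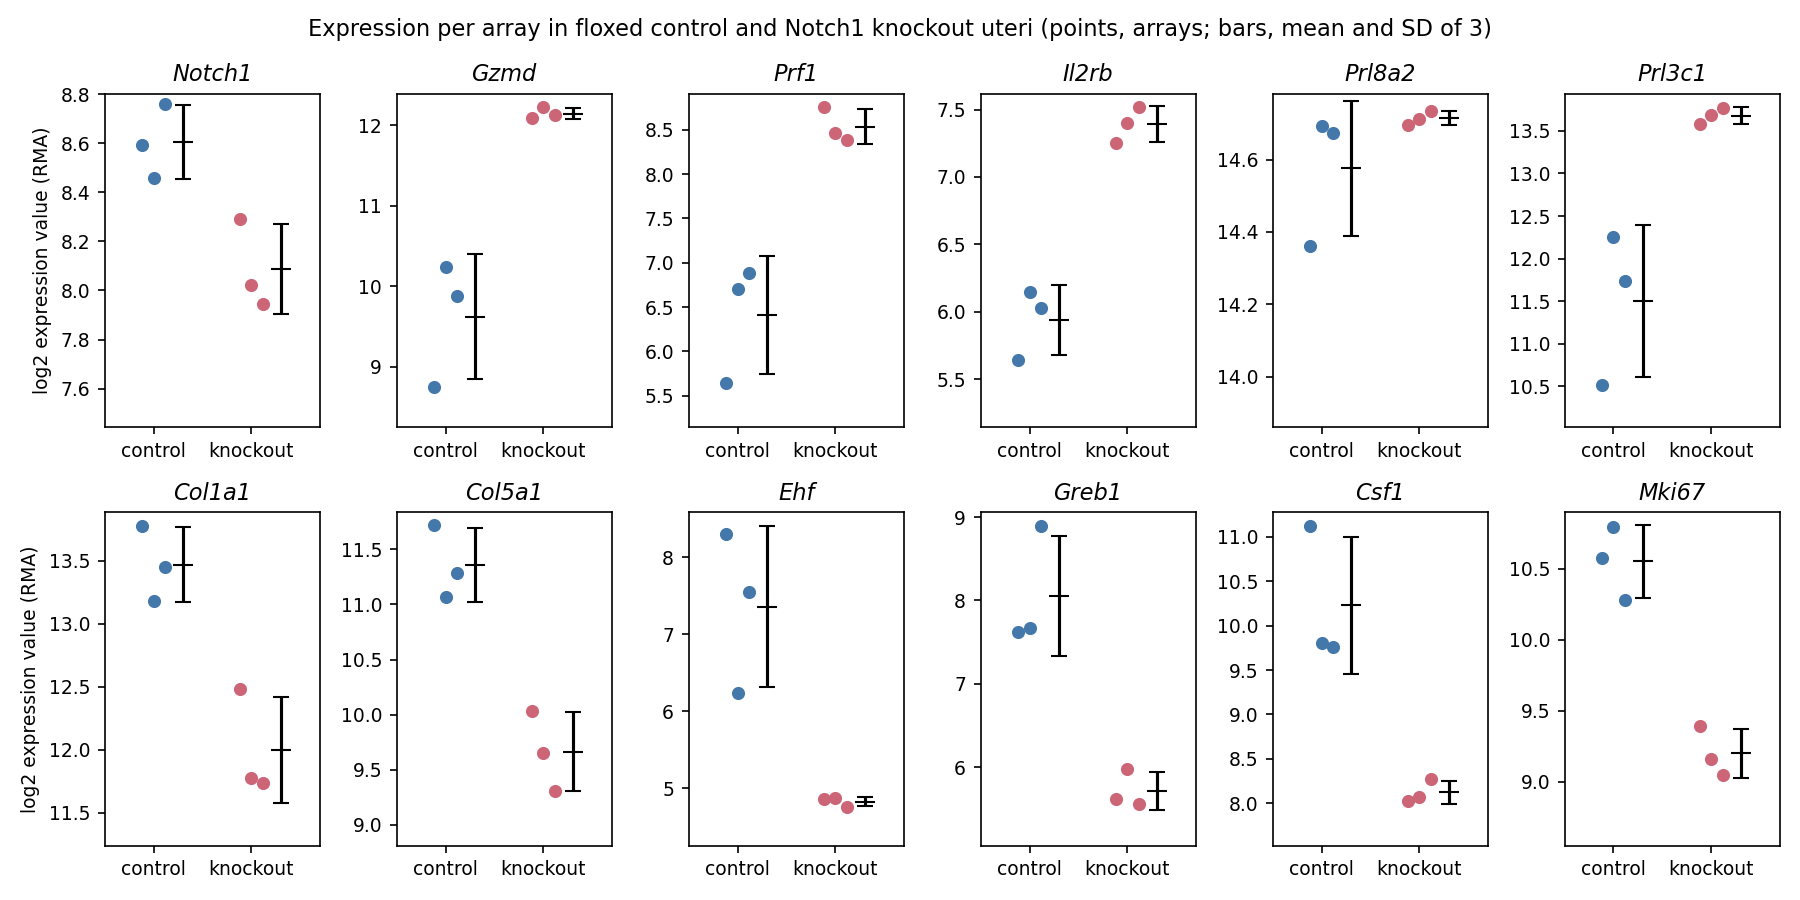
Expression of 12 genes in each array, as log2 RMA values on the vertical axis of each panel, with its own scale, for floxed control and Notch1 knockout uteri. Coloured points are arrays, and black bars are the mean and SD of 3 arrays. Gzmd lay near 12 in every knockout array and near 9 to 10 in the controls, and Col1a1 lay below 12.5 in every knockout array and above 13 in the controls. Prl8a2 lay at the highest value of its array in 5 of the 6 arrays.

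Of 18193 genes, 998 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 484 higher and 514 lower in the knockout. At least 2-fold differences were found for 388 of them, 141 higher and 247 lower. The median difference over all genes was 0.06. With each array centred on its median it was 0.18, and 1005 genes were then higher and 461 lower. The groups did not overlap for 5440 genes, 29.9% of all. Where no values tie, the mean share over the 10 ways of splitting the 6 arrays is 10% by arithmetic. Genes that vary together can lift the share of any 1 split, and other splits were not computed. The share therefore does not tell a difference between the groups from other structure among the arrays. The count of 998 genes depended on single arrays. It was 164 without control array 1, 3152 without control array 2, 193 without control array 3 and 501 without knockout array 1. It was 0 in limma without knockout array 2 or without knockout array 3, where 3239 and 3213 genes had an unadjusted p below 0.05 and an ordinary two-sample test also called 0. In each of these fits all 998 genes kept an unadjusted p below 0.05 in limma, but they had been chosen on the same arrays. Their direction could not change, because the groups did not overlap for any of the 998.

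Of the 18 measured natural killer cell markers, 11 passed the test, all higher, with 15 when adjusted over the list alone. Over all 18 members the median was 1.52, and 17 had a higher mean in the knockout. Il2rb, the receptor chain shared by interleukin 2 and interleukin 15, rose by 1.45 ± 0.16, and Nkg7, a cytotoxic granule protein, rose by 1.06 ± 0.15. A second Il2rb probe set, at 6.30 in controls against 5.94 for the one used, differed by 0.455 and did not pass. Eomes, Klrg1 and Ncr1, named after their values were seen, rose by 0.75, 1.60 and 0.67. They encode a transcription factor and 2 surface receptors found in natural killer cells. camera with the preset correlation called the list (adjusted p = 2.13e-09), and the adjusted p = 0.514 with an estimated correlation. The list median was 1.01 when all probe sets of a gene were averaged. The number past the gene test and higher was 7 without control array 1, 13 without control array 2, 3 without control array 3 and 4 without knockout array 1. No member passed without knockout array 2 or without knockout array 3.

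Of 21 measured fibroblast markers, 6 passed and were lower, 10 when adjusted over the list alone, and 20 had a lower mean in the knockout. Besides Col1a1 and Col5a1 they were the collagens Col6a2 at -1.22 ± 0.17 and Col5a2 at -0.88 ± 0.15 and, named after their values were seen, Fn1 (fibronectin) at -1.26 and Pdgfrb, a growth factor receptor of fibroblasts and pericytes, at -1.09. As a list they had a median of -0.70 (camera, adjusted p = 2.13e-09), and the adjusted p = 0.514 with an estimated correlation. The number past the test and lower was 2 when all probe sets of a gene were averaged, 1 without control array 1 or without control array 3, 13 without control array 2, 5 without knockout array 1 and 0 without knockout array 2 or without knockout array 3. A second, dimmer probe set of Col1a1 differed by 0.08 and did not pass. Among matrix remodelling enzymes and inhibitors, 3 of 24 fell and 1 rose, with the same counts when adjusted over the list alone. Mmp12 and Mmp14, matrix metalloproteinases, were at -1.44 ± 0.28 and -0.87 ± 0.19, the metalloproteinase Adamts9 was at -1.08 ± 0.12, and Plaur, the urokinase receptor, rose by 0.68 ± 0.16. The enzymes had a median of -0.46 (camera, adjusted p = 0.00747), and the adjusted p = 0.593 with an estimated correlation. Their mean deviation over the list was -0.21 in control array 2 and 0.16 in knockout array 1, so the groups overlapped. Among genes above the median level the median was -0.34 and camera no longer called the list (adjusted p = 0.0523).

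Smooth muscle markers had a median of -0.42, and 17 of 18 had a lower mean in the knockout, but 0 passed the limma gene test, or when adjusted over the list alone. Myh11 and Acta2, the smooth muscle myosin and actin, were at -1.91 ± 0.53 and -0.43 ± 0.15, and Mylk, the myosin kinase, was at -0.76 ± 0.25. camera called the list (adjusted p = 0.000535), and the adjusted p = 0.656 with an estimated correlation. That median was -0.25 without control array 1 and -0.86 without control array 2, and the groups overlapped. The mean deviation over the list was 0.82, -0.54 and 0.56 in control arrays 1, 2 and 3 and 0.02, -0.41 and -0.46 in knockout arrays 1, 2 and 3. The 3 arrays with the highest values, control arrays 1 and 3 and knockout array 1, also had the smallest 3' minus 5' difference of the beta-actin control, 0.37, 0.63 and 0.39, against 0.85, 0.94 and 1.11 in control array 2 and knockout arrays 2 and 3. The same 3 arrays were the highest for the epithelial markers, the matrix enzymes and the BMP, TGF-beta and activin genes. They were also the highest for the endothelial, neutrophil, anti-apoptotic, interferon and immediate early lists, which camera did not call. Of the other called lists, the natural killer list was highest in the 3 knockout arrays and the rest in the 3 control arrays. The 3' minus 5' difference of the Gapdh control did not set control arrays 1 and 3 and knockout array 1 apart. It was 0.01, 0.02 and 0.10 in control arrays 1, 2 and 3 and 0.01, 0.07 and 0.46 in knockout arrays 1, 2 and 3. With the actin difference as a covariate the smooth muscle median was -0.28.

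Of 24 measured epithelial markers, 5 passed and were lower, also 5 when adjusted over the list alone, and 19 had a lower mean. Ehf, Grhl2 (-1.13 ± 0.15), Esrp1 (-1.76 ± 0.31), Sox9 (-0.66 ± 0.13) and Cdh1 (-0.84 ± 0.18) encode epithelial transcription factors, a splicing factor and E-cadherin. The epithelial median was -0.72 (camera, adjusted p = 5.66e-06), and the adjusted p = 0.593 with an estimated correlation. The mean deviation over the list was 0.80, -0.39 and 0.64 in control arrays 1, 2 and 3 and -0.08, -0.63 and -0.34 in knockout arrays 1, 2 and 3, so control array 2 lay below knockout arrays 1 and 3. Of 20 estrogen-induced epithelial genes, 4 passed and were lower, 8 when adjusted over the list alone. They were Greb1, Csf1, the growth factor of macrophages, at -2.11 ± 0.34, Fgf9, a fibroblast growth factor, at -1.23 ± 0.22, and Padi4, which converts arginine to citrulline in proteins, at -1.05 ± 0.18. Their median was -1.19 (camera, adjusted p = 2.89e-06), and the adjusted p = 0.514 with an estimated correlation. It was -0.48 among genes above the median level. The estrogen receptor gene Esr1 was at -0.58 ± 0.32 and did not pass. Pigr, which carries immunoglobulins across epithelia, at -2.74 ± 0.42 and Ccl28, a chemokine of mucosal epithelia, at -2.16 ± 0.36 were among the 12 largest falls.

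The other large falls, among the 12 genes named by size in each direction, were Sgms2, a sphingomyelin synthase, at -2.90 ± 0.26, Zfhx3, a zinc finger and homeobox transcription factor, at -2.39 ± 0.21, Tmprss11a, a transmembrane serine protease, at -2.29 ± 0.23, and Ttc28 at -2.25 ± 0.24. F5, coagulation factor V, was at -2.14 ± 0.22, Prrc2c at -2.09 ± 0.34 and Slc39a8, a zinc transporter, at -2.02 ± 0.36. Besides the granzymes, the largest rises were those of Mgst2, a microsomal glutathione S-transferase, by 2.79 ± 0.19, and Pkd2l1, a cation channel of the polycystin family, by 2.66 ± 0.26. Gpld1, which cleaves the lipid anchor of surface proteins, rose by 2.44 ± 0.26, Nmnat2, an enzyme of NAD synthesis, by 2.37 ± 0.32, Mab21l4 by 2.36 ± 0.22, Qrfpr, a neuropeptide receptor, by 2.35 ± 0.23 and Gdpd2, a glycerophosphodiester phosphodiesterase, by 2.24 ± 0.24. Their limma adjusted p ran from 0.00814 to 0.0378 over the 24 genes named by size.

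**Figure D2:**
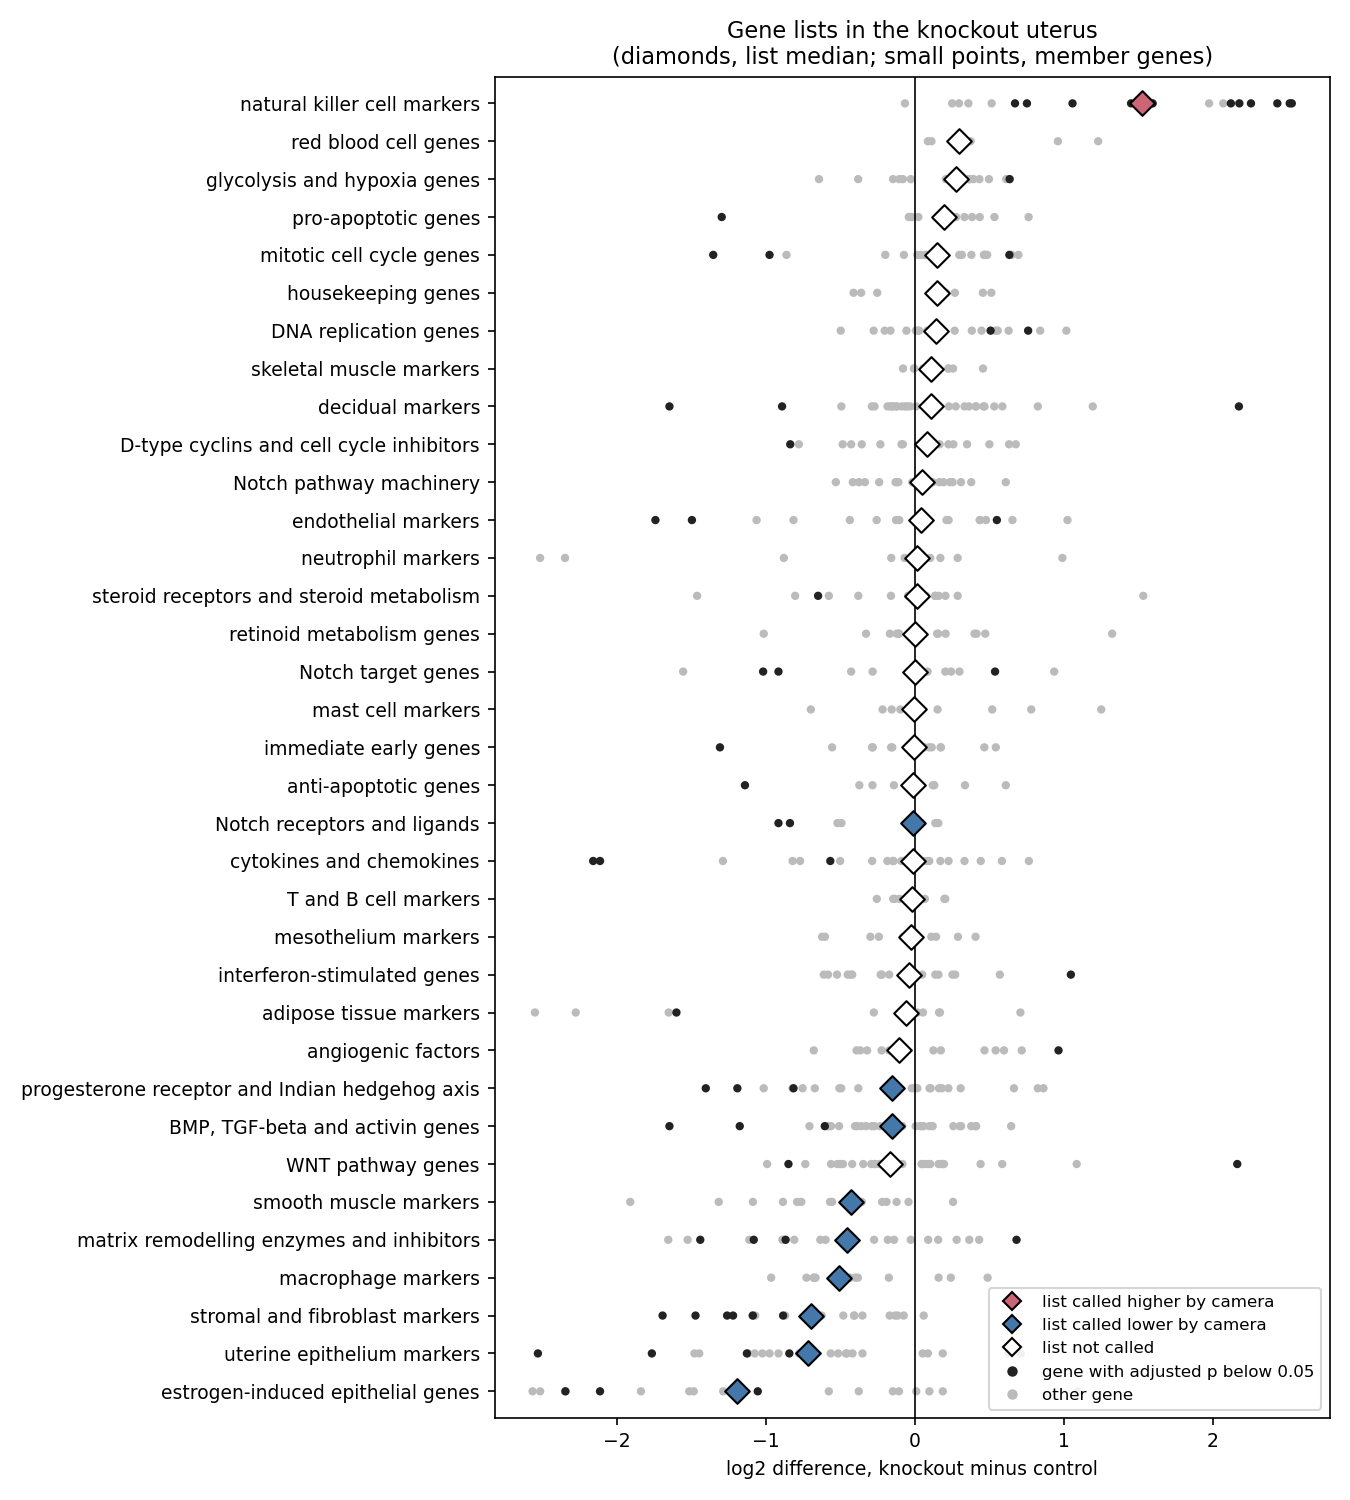
Log2 difference, knockout minus control, on the horizontal axis, for 35 gene lists ordered by their median. Diamonds are list medians, coloured where camera with the preset correlation called the list, and small points are member genes, black where the limma adjusted p was below 0.05. Natural killer cell markers stand at a median of 1.52, above all other lists, and estrogen-induced epithelial genes stand lowest at -1.19.

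Among 9 Notch receptors and ligands, Notch2 and Notch3 fell by 0.84 and 0.91 on the log2 scale and no member rose, with 4 lower when adjusted over the list alone. The ligand gene Jag1 was at -0.49 ± 0.12 and did not pass. camera called the list as lower (adjusted p = 0.043), and the adjusted p = 0.514 with an estimated correlation. The list median was -0.01 and had no settled sign. It was 0.10 with arrays centred on their medians, 0.02 after quantile normalization, -0.24 with array weights and -0.49 among genes above the median level. Leaving out 1 array gave -0.24 without control array 1, -0.14 without control array 2, 0.11 without control array 3, -0.07 without knockout array 1, 0.02 without knockout array 2 and -0.26 without knockout array 3, and the call was lost in 6 of 15 alternative fits and in 2 other list tests besides the estimated correlation. Among 14 Notch target genes, Nrarp, a feedback inhibitor of Notch signalling, rose by 0.54 ± 0.11, while Snai2, a transcription factor that represses E-cadherin, was at -1.02 ± 0.22 and fell, as did Notch3. Adjusted over the list alone 1 was higher and 3 were lower. None of 19 genes of the Notch pathway machinery passed limma, 0 also when adjusted over the list alone, and Mib1, a ligand ubiquitin ligase, was at -0.53 ± 0.13. Neither of these lists was called.

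Decidual markers were not called as a list. Of 37 measured, 1 rose and 2 fell, the same counts as when adjusted over the list alone, and the median was 0.11. Prl3c1, a prolactin family member, rose by 2.18 ± 0.39, while Inhbb, a subunit of activin and inhibin, fell by 1.65 and Egfr, the epidermal growth factor receptor, by 0.89. Averaged over its 7 probe sets, Egfr differed by -0.06. Prl8a2, an abundant decidual product of the prolactin family, was at 14.58 ± 0.19 (SD, n = 3) in control and 14.71 ± 0.02 (SD, n = 3) in knockout arrays. It was the highest value of the array in 5 of the 6 arrays, so a rise could not have shown there. Of the other decidual and receptor genes fixed for naming, none passed limma except Bcl2. Cebpb was at 0.46 ± 0.14, Ptgs2 at 1.20 ± 0.41, Hoxa10 at 0.83 ± 0.31, Bmp2 at 0.41 ± 0.35, Wnt4 at -0.16 ± 0.30 and Ccnd3 at 0.11 ± 0.13. Like Wnt4 and Ccnd3, Hoxa11 (0.11 ± 0.22), Hand2 (0.16 ± 0.21) and Igfbp1 (0.01 ± 0.14) lay within 1 SE of 0. The progesterone receptor gene Pgr was at -0.38 ± 0.15 by its brightest probe set and at 0.44 by a dimmer one, and neither passed. Bax was not analysed here.

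Of 25 genes of the progesterone receptor and Indian hedgehog axis, 3 fell, with 7 lower and 1 higher when adjusted over the list alone. They were Ncoa1, a steroid receptor coactivator, at -1.19 ± 0.13, and the hedgehog transcription factors Gli2 at -1.40 ± 0.25 and Gli3 at -0.81 ± 0.17. The list median was -0.15 (camera, adjusted p = 0.0186), and the adjusted p = 0.514 with an estimated correlation. Without control array 3 the median was -0.04 and camera no longer called the list. With the 3' to 5' ratio of beta-actin as a covariate the median was -0.14 and camera's adjusted p = 0.0519. It was -0.04 with each array centred on its median, where the median over all genes was 0.18, and -0.29 with array weights. Of 34 BMP, TGF-beta and activin genes, Tgfb2 at -1.17 ± 0.17, Smad3 at -0.60 ± 0.12 and Inhbb fell, also 3 when adjusted over the list alone. The list median was again -0.15 (camera, adjusted p = 0.0108), and the adjusted p = 0.514 with an estimated correlation. It was -0.07 without control array 3 and -0.25 without control array 2. The list means of the groups overlapped, with the highest in control arrays 1 and 3 and knockout array 1. The median was -0.07 with the actin covariate, -0.04 with each array centred on its median and -0.22 with array weights. After a correction for gene length it was -0.20 and among genes above the median level -0.15, and camera called the list in neither (adjusted p = 0.0973 and adjusted p = 0.0803). Of 31 WNT pathway genes, the secreted inhibitor Wif1 rose by 2.17 ± 0.33 and another one, Sfrp2, was lower at -0.85 ± 0.14, the same counts as when adjusted over the list alone, and the list was not called. Wif1 had a mean of 3.16 in the control arrays, near their lowest values of 2.61 to 2.75, so the size of its rise is uncertain.

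None of the cell cycle lists was called. Of 21 mitotic genes, 16 had a higher mean in the knockout and 5 a lower one. Mki67, a proliferation marker, at -1.35 ± 0.17 and Cenpf, a kinetochore protein, at -0.97 ± 0.17 fell, against most of the list. The mitotic kinesin Kif20a rose by 0.64 ± 0.13. Adjusted over the list alone 4 were higher and 3 lower. Of 22 DNA replication genes, 17 had a higher mean in the knockout and 5 a lower one. Gins2 rose by 0.76 ± 0.16 and Prim1 by 0.51 ± 0.12, with 3 higher and 0 lower when adjusted over the list alone. Of 17 D-type cyclins, their kinases and cell cycle inhibitors, Cdk6 fell by 0.83 on the log2 scale, and 1 was higher and 1 lower when adjusted over the list alone. Of 15 pro-apoptotic genes, Bcl2l11 was lower at -1.29 ± 0.21, with 3 higher and 1 lower when adjusted over the list alone. Of 8 anti-apoptotic genes, Bcl2 was lower at -1.14 ± 0.24, also 1 when adjusted over the list alone.

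Of 18 endothelial markers, Vwf, von Willebrand factor, at -1.74 ± 0.25 and Ptprb, a receptor phosphatase of vessels, at -1.49 ± 0.18 fell, while Emcn, a surface sialomucin, rose by 0.55 ± 0.11. Adjusted over the list alone 2 were higher and 4 lower. Of 18 angiogenic factors, Sphk1, a sphingosine kinase, rose by 0.97 ± 0.20, with 3 higher and 1 lower when adjusted over the list alone. Neither list was called. Macrophage markers had a median of -0.51 and 14 of 17 had a lower mean, but 0 passed the limma gene test, with 2 lower when adjusted over the list alone. Adgre1, which encodes the macrophage antigen F4/80, was at -0.52 ± 0.12 and Ctss, a lysosomal protease, at -0.73 ± 0.17. camera called this list (adjusted p = 0.000402), and the adjusted p = 0.516 with an estimated correlation. Its median was -0.27 without control array 1. Of 29 cytokines and chemokines, Csf1, Ccl28 and Cxcl14 (-0.57 ± 0.13) fell, also 3 when adjusted over the list alone, and Il15, which supports natural killer cells, was at 0.77 ± 0.23 and did not pass.

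Several remaining lists had 1 gene past the test in limma and none was called. Hsd17b11 was lower by this test at -0.65 ± 0.14 among 18 genes of steroid metabolism, Usp18 was higher by 1.05 ± 0.22 among 20 interferon-stimulated genes, and Egln3, a prolyl hydroxylase that responds to hypoxia, was higher by 0.64 ± 0.14 among 18 genes of glycolysis and hypoxia. Egr1 was lower at -1.31 ± 0.29 among 17 immediate early genes. When adjusted over the list alone, these lists had 1 higher and 1 lower, 2 higher and 4 lower, 1 higher, and 1 lower. Of 16 retinoid metabolism genes, 15 T and B cell markers, 10 mast cell markers, 10 mesothelium markers and 12 skeletal muscle markers, 0 passed in limma, 0 also when adjusted over the list alone. Of 10 housekeeping genes 0 passed, with 2 higher and 1 lower when adjusted over the list alone. For 8 of the lists that were not called, the median, the mean and the direction of the test did not all have one sign.

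Longer genes were lower in the knockout arrays. In the decile of genes with the shortest genomic length, with a median of 2.03 kb, 4.77% were called higher and 0.222% lower, and in the decile with the longest, with a median of 199.8 kb, 1.5% were called higher and 10.8% lower. Across genes, which are not independent replicates, the Spearman correlation of length and difference was -0.24. The correlation of length with each array's deviation from the gene means was 0.16, 0.13 and 0.19 in control arrays 1, 2 and 3 and -0.15, -0.15 and -0.24 in knockout arrays 1, 2 and 3. After a correction for length chosen after this was seen, 670 of the 998 genes were still called, the medians were 1.44 for natural killer cell markers, -0.75 for fibroblast markers, -0.80 for epithelial markers and -1.27 for estrogen-induced genes, and camera called these 4 lists. In that fit the estimated correlation gave an adjusted p = 0.478, 0.566, 0.586 and 0.566 for them in camera. Control array 2 stood apart from the other 5 on the second principal component, which held 25.4% of the variance, and its level of the fat cell gene Adipoq was 8.79, against 6.52 and 6.37 in the other control arrays. The first component, with 55.0%, separated the groups.

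**Figure D3:**
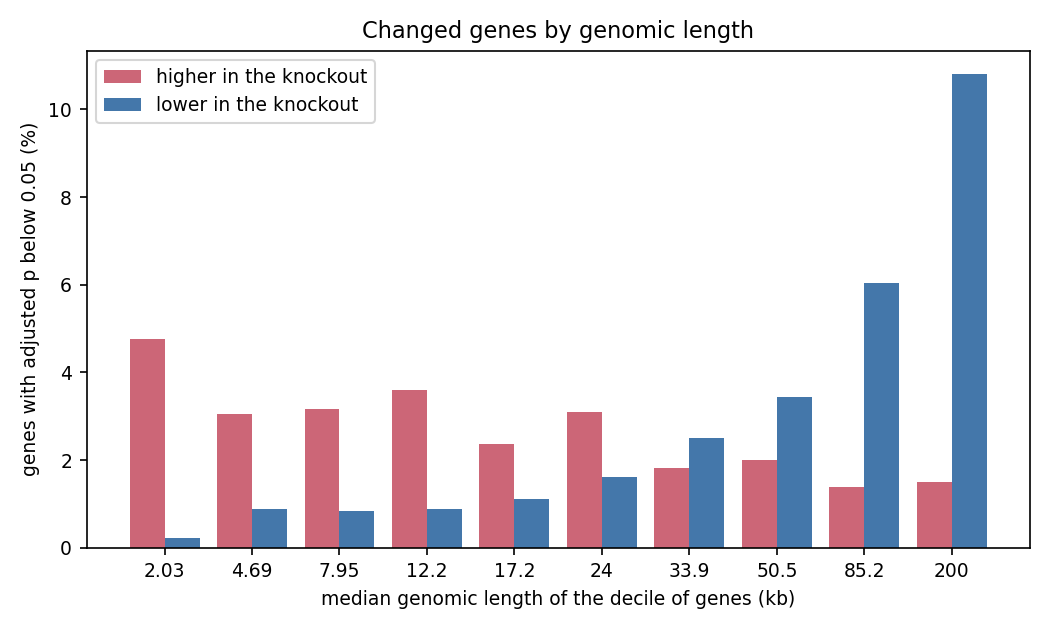
Percent of genes with a limma adjusted p below 0.05 on the vertical axis, by deciles of genes ordered by genomic length, each labelled with its median length in kb. Red bars are genes higher and blue bars genes lower in the knockout. The share of lower genes was 0.222% in the shortest decile and 10.8% in the longest.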

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

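This signal was looked up after the main results were seen. Probe sets that the platform table pairs with no gene or with several genes entered no comparison above. Of 10092 such probe sets, 148 passed an adjusted p of 0.05 in limma over all probe sets, 23 higher and 125 lower in the knockout. Probe sets 1422400_a_at and 1422179_at were higher by 1.75 ± 0.28 and 1.58 ± 0.28 (SE, n = 3 per group), and 1455869_at and 1431213_a_at were lower, at -3.27 ± 0.55 and -3.07 ± 0.49. Their genes are not named here, and no explanation was tested. No formal test of single outlying arrays was run on these groups of 3, though fits with array weights and without each array were made. The series holds 1 contrast, so no effect could be compared between groups.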

How the results depend on the processing

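The length correction and the actin covariate were chosen after the data were seen. Of the 78 named genes that passed, all kept their direction in every fit in which they were tested. For the left-out arrays this was fixed in advance, because the groups did not overlap for any of these genes. Averaging all probe sets of a gene left 49 of them called, the length correction 62, the actin covariate 56, quantile normalization 73 and centring on array medians 74. Without knockout array 2 or knockout array 3 limma called 0. Signal over background was not used here, so dim probe sets set no floor. Simulated changes of 0.5 were recovered in 3.6% of cases where 200 genes were changed, a share that need not hold for these arrays. Where no cause is named below, the cause was not tested.

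The count of 998 genes, 484 higher and 514 lower, was 4614 with array weights, 2516 higher and 2098 lower. It was 593 with the actin covariate, of which 235 were higher. Stricter limits left 388 genes at 2-fold, 141 higher and 247 lower, and 25 at an adjusted p of 0.01 in limma, 12 higher and 13 lower. An ordinary two-sample test called 1 gene, 0 higher and 1 lower, against 4480 at an unadjusted p below 0.05 in limma. Higher genes numbered 1005 with centred arrays, 308 after the length correction and 294 when probe sets were counted, and 332 genes were lower with averaged probe sets. Leaving out 1 array gave 0 to 3152 genes, 0 to 1533 higher and 0 to 1619 lower. The 0 came without knockout array 2 or 3 (3239 and 3213 genes at an unadjusted p below 0.05 in limma), and the highest counts came without control array 2.

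Whether the numbers shared by control and knockout arrays pair them is not known, and they were not treated as pairs in the main fit. Deviations from the group means correlated at 0.376, 0.165 and -0.051 for numbers 1, 2 and 3. Knockout arrays 1 and 2 correlated best with the control array of the same number, and knockout array 3 with control array 2. With the replicate block 1439 genes were called, 778 of them lower.

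Notch1 passed with array weights at -0.63 and without control array 2, and ranged from -0.62 to -0.44 over the left-out arrays. Of 10 lists called by camera, 0 were called with an estimated correlation, and fry called 2 of 35. The natural killer, fibroblast, epithelial, estrogen-induced, smooth muscle and macrophage lists were called in all 15 other fits, and the Notch receptor list was lost in 6 of them.

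Of the genes that did not pass, Pgr was at 0.028 with averaged probe sets. Hoxa11 was at -0.019 with array weights and at -0.028 after the length correction, and ranged from -0.13 to 0.26 over the left-out arrays. Igfbp1 was at -0.001 after quantile normalization, -0.12 after the length correction and -0.017 with the actin covariate, and ranged from -0.086 to 0.10. Over the left-out arrays Bmp2 ranged from -0.027 to 0.69, Hand2 from -0.046 to 0.37 and Wnt4 from -0.39 to 0.12.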

Other observations

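The tests of RNA integrity, of a diluted main tissue and of granzyme cross-hybridization were chosen after the results were seen. So were those of a lower fibroblast share and of the genes beside Pgr, the length correction and the actin covariate. The tests of low-signal noise, of length in each list and of other splits of the arrays had their outcomes stated before they were run. The test of length in each list still used the correction chosen after the data were seen. Red blood cell genes had a higher mean in the knockout for all 7 measured members, with a median of 0.30. None passed the limma gene test, and 1 was higher when adjusted over the list alone. The list was called by fry (adjusted p = 0.0072) but not by camera (adjusted p = 0.109). Of the 13 genes in the list only these 7 were measured, and 2 of them lay above the median level of all genes in controls. Slc4a1, the anion exchanger of the red cell membrane, was at 0.96 ± 0.23 and Alas2, which starts heme synthesis in red cells, at 1.23 ± 0.48. Of 12 neutrophil markers 0 passed in limma, with 1 higher and 1 lower when adjusted over the list alone. Ltf and Lcn2, secreted iron-handling proteins that estrogen also induces in uterine epithelium, were at -2.51 ± 0.70 and -2.35 ± 0.86, and S100a8 was at 0.99 ± 0.25.

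Of 11 adipose markers, Pck1, an enzyme of glucose synthesis, fell by 1.60 on the log2 scale, with 1 higher and 4 lower when adjusted over the list alone, and camera did not call the list (adjusted p = 0.131). Adipoq was at 6.52, 8.79 and 6.37 in control arrays 1, 2 and 3 and at 4.76, 5.57 and 3.71 in knockout arrays 1, 2 and 3. Its difference of -2.55 ± 0.70 did not pass.

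Of 18 natural killer cell markers 11 rose, with a list median of 1.52, and camera gave an adjusted p = 0.514 with an estimated correlation. A trend with gene length is argued against, since the median was 1.44 after the length correction. A smaller share of the main tissue, which would raise all other cell types alike, is argued against too, as the median exceeded those of the macrophage, T and B cell, mast cell and endothelial lists by at least 1.48. The macrophage and endothelial lists carry this argument, with 13 of 17 and 18 of 18 members above the median level in controls. Only 1 of 15 T and B cell and 2 of 10 mast cell markers lay above it, so those lists may not show a rise. Cross-hybridization among granzyme genes is argued against as the cause of the whole list, as 6 of 11 members other than granzymes were past the threshold and higher. These 6 include Il2rb, of which a second probe set, at 0.455, did not pass. For the granzymes themselves cross-hybridization stays open, because other genes cannot show whether granzyme probe sets read one another. Gzmc, Gzmd, Gzme, Gzmf and Gzmg rose by similar amounts, 2.18 to 2.53, and may not be separate rises. A larger number of natural killer cells in the knockout uterus may account for the rise, as a hypothesis, as may higher expression per cell or a difference in the day of collection, which were not tested; 0 of the 18 markers are in another list, 7 lie above the median level of all genes in the control arrays, and the brightest, Gzmd, was at 12.14 in the knockout.

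Of 21 fibroblast markers 6 fell, with a list median of -0.70, and camera gave an adjusted p = 0.514 with an estimated correlation. A trend with gene length is argued against as the whole cause, since the median was -0.75 after the length correction. A smaller share of fibroblasts stays open, because members other than collagens had a median of -0.40 and collagens one of -1.08, which neither agree nor lie apart enough to exclude it. Less collagen made per cell may account for the gap between them, and this was not tested.

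Longer genes were lower in the knockout. Noise of dim genes is argued against, since the correlation of length and difference was -0.34 among genes above the median level. RNA integrity may contribute and stays open, because only 2 knockout arrays exceeded all control arrays in the 3' minus 5' difference of the beta-actin control, and the group means differed by 0.20. That difference was 0.37, 0.85 and 0.63 in control arrays 1, 2 and 3 and 0.39, 0.94 and 1.11 in knockout arrays 1, 2 and 3. Control array 1 and knockout array 1 were thus close, but their correlations with length were 0.16 and -0.15. For control array 2 and knockout array 2 these were 0.13 and -0.15. As far as the actin difference measures it, integrity is argued against as the whole cause. Knockout array 3, the highest at 1.11, did have the lowest correlation with length, -0.245. For the Gapdh control only knockout array 3, at 0.46, exceeded all control arrays, which were at 0.01, 0.02 and 0.10, while knockout arrays 1 and 2 were at 0.01 and 0.07. With the actin difference as a covariate 593 genes were called, 549 of them among the 998.

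The 6 arrays can be split into groups of 3 in 10 ways. The real split gave 998 genes and the highest other gave 0, and 1 of the 10 splits, the real one, gave as many. For lists called by camera the real split gave 10 and 3 of the 10 splits gave as many. The highest other gave 17 and set control arrays 1 and 3 with knockout array 1 against the rest. Too few splits exist for a share under 0.05. The split with 17 lists points to a structure of the samples. It is also the split by the actin 3' minus 5' difference, which was 0.37, 0.63 and 0.39 in these 3 arrays and 0.85, 0.94 and 1.11 in the others, though not by that of the Gapdh control, and knockout array 1 correlated with control array 3 at 0.989, as closely as with knockout array 2.

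Cre inserted at Pgr could carry flanking variants of another strain that alter nearby genes. Among 82 measured genes nearest to Pgr, up to 50 on each side, 3.66% were called, against 5.49% of all other genes (two-sided Fisher's exact p = 0.629), a difference too small to decide.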
